A study of Mus musculus with 34 samples.

How the data were processed

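Mouse CD4 T cells were sorted from lymph nodes and spleen of C57BL6/J mice with a Foxp3-IRES-hCD2 reporter, in which human CD2 on the surface marks Foxp3-expressing cells. Per the labels, Treg cells were CD4+hCD2+ and Tconv cells CD4+hCD2-. Central Treg cells were sorted as high in CCR7 and low in CD44 and effector Treg cells as low in CCR7, among other surface markers. R397W Treg cells were sorted as CD4+hCD2+GFP- from mice with a Foxp3 R397W hCD2 allele and a wild-type Foxp3 GFP allele, and their controls had a wild-type hCD2 allele in its place. The series holds 34 samples, of which 24 are chromatin immunoprecipitations of BATF, Foxp3 or IRF4 and 10 are input DNA. The labels name an anti-BATF clone and an in-house anti-Foxp3 antibody, but no antibody for IRF4. The input libraries have no columns in the deposited tables and were not used.

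The authors deposited 4 tables of normalised peak scores in a unit of signal. There are 2 tables for BATF and 1 each for Foxp3 and IRF4, and each has 1 list of peaks for all its libraries, mostly 400 bp long. Per the submitters' processing notes, Bowtie2 2.4.1, MACS2 2.2.7.1, edgeR 3.38.4 and DiffBind 3.12.0 were used with genome build mm10, without their roles or order, and the filters are not stated. All sample columns were matched to labelled samples. The columns of the R397W controls carry other replicate numbers than their titles, so only their group is known. Every deposited value was a whole multiple of 1 step per library within 0.01, so each value was taken as reads in a peak times 1 scale factor, and whole reads were recovered. The deposited factors lay within 0.884% (first BATF table), 5.14% (second BATF table), 2.14% (Foxp3) and 1.28% (IRF4) of those from edgeR's TMM method over the same peaks. A change in binding common to most peaks would therefore be scaled away. Total sequencing depth is unknown, and only reads in peaks are given. The Treg and Tconv libraries are the same in both BATF tables: in 402 intervals common to both, recovered reads were equal but for 1 read in 1 interval of 1 Tconv library. Tables were fitted separately.

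Peaks were compared with limma 3.58.1 in R 4.3.3 on log2 of value plus 1, with empirical Bayes moderation and a trend of the spread on the mean. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all peaks of a table, and an adjusted p under 0.05 was called higher or lower. There were 5 comparisons: BATF and IRF4 in Treg against Tconv cells, Foxp3 in Batf knockout against wild-type Treg cells and in effector against central Treg cells, and BATF in R397W against control Treg cells. Both Foxp3 comparisons came from 1 fit of 8 libraries, and the R397W comparison used its own 4 libraries. Folds are on the scale of value plus 1. All peaks were kept. Recovery was tested on simulated data with 100 changed peaks. At 2-fold, limma recovered 63% for BATF and 30% for IRF4 in Treg against Tconv cells, 28% for the Batf knockout, 38% for effector against central Treg cells and 14% for R397W. At 4-fold these were 99%, 88%, 96%, 98% and 72%. False calls made up 6.90% of the simulated calls for BATF in Treg against Tconv cells, above the threshold of 0.05. In the other comparisons they made up 1.59% to 3.55%. The value of 3 reads was taken as the floor of a library.

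Each peak was assigned to the nearest protein-coding gene body within 100000 bp (GRCm38.p6, the same assembly as mm10), ties going to the nearest gene end. The plan was to use the nearest transcription start site, but the annotation at hand has neither strand nor exons. Of the peaks 97.5%, 96.4%, 94.8% and 95.0% were assigned in the first and second BATF, Foxp3 and IRF4 tables, and 58.7%, 58.9%, 67.0% and 55.7% of the peaks lay in a gene body. Coordinates are printed as deposited, and whether they count from 0 or 1 is not settled. No genome sequence was at hand, so classes of peaks by motif were not tested.

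The groups of samples, the comparisons, the tests, 11 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were Treg core genes, effector Treg genes, central or naive T cell genes, AP-1, BATF and IRF factors, T helper lineage factors and cytokines, T cell receptor and costimulatory signalling genes, Foxp3 partner factors, markers of B cells, of myeloid cells and of CD8 and NK cells, and housekeeping genes. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation, adjusted over the lists of a comparison, and members were also adjusted over the list alone. With an estimated correlation, camera takes its degrees of freedom from the libraries and not the peaks. With so few libraries a call is then hard to reach, whatever the correlation. A list with under 3 peaks was not tested. The named peaks were the strongest assigned peak of each of 27 focus genes, up to 3 member genes of each list by smallest p, and the 6 largest log2 fold changes per direction among strong peaks. A strong peak is a called peak with a mean log2 value above the median of its table, replicate ranges that do not overlap and a nearest gene not yet taken. Statements on the largest rise or fall hold for strong peaks only.

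Peaks of different tables were matched when they overlapped by at least 1 bp with GenomicRanges 1.54.1. Calls in common were tested with Fisher's exact test (two-sided, peaks taken as independent) over 10 pairs of comparisons, with Benjamini and Hochberg adjustment. Classes of peaks on or off a peak of another factor were tested with camera. Alternatives were pseudocounts of 0.1 and 10, a filter at the 25th percentile, median-of-ratios, quantile and trimmed-mean scaling, no trend of the spread, a log2 threshold of 1, leaving out each library, the replicate number as a block, only the 4 libraries of the compared Foxp3 groups, a reciprocal overlap of 50%, only the stronger partner peaks, BATF partner peaks of the second table, only the stronger BATF peaks, and a window of 20000 bp for genes. Chosen after the data were seen were edgeR 4.0.16 (quasi-likelihood, on recovered reads), a fit of all 8 libraries of the second BATF table, and class tests within the stronger Foxp3 or IRF4 peaks. The labels do not say whether replicates are separate animals, so the p-values measure only the spread between these samples, which may be technical.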

Results

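The binding of 3 transcription factors was measured by chromatin immunoprecipitation and sequencing in mouse CD4 T cells sorted from lymph nodes and spleen. Foxp3 is the lineage factor of regulatory T (Treg) cells. BATF is an AP-1 family factor, and IRF4 is an interferon regulatory factor that binds DNA together with BATF. BATF was measured in Treg and conventional CD4 T (Tconv) cells, with 2 libraries each. It was also measured in Treg cells that carry the Foxp3 mutation R397W and in their wild-type controls, with 2 libraries each. IRF4 was measured in Treg and Tconv cells, with 4 libraries each. Foxp3 was measured in effector Treg cells (low CCR7), central Treg cells (high CCR7, low CD44), all wild-type Treg cells and all Treg cells of Batf knockout mice, with 2 libraries each. There were 16109 BATF peaks for Treg and Tconv cells, 9973 BATF peaks for the R397W experiment, 9134 IRF4 peaks and 6396 Foxp3 peaks. Reads within peaks ranged from 1377509 to 2280493 per library in the first BATF table and from 144319 to 1009580 in the second. They ranged from 162580 to 336969 for IRF4 and from 164740 to 393310 for Foxp3. Values below are normalised reads per peak, as mean ± SD over libraries, on the mm10 genome. Adjusted p-values of peaks are from limma. A peak is named after the nearest protein-coding gene within 100000 bp, which need not be the gene it regulates.

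**Figure D1:**
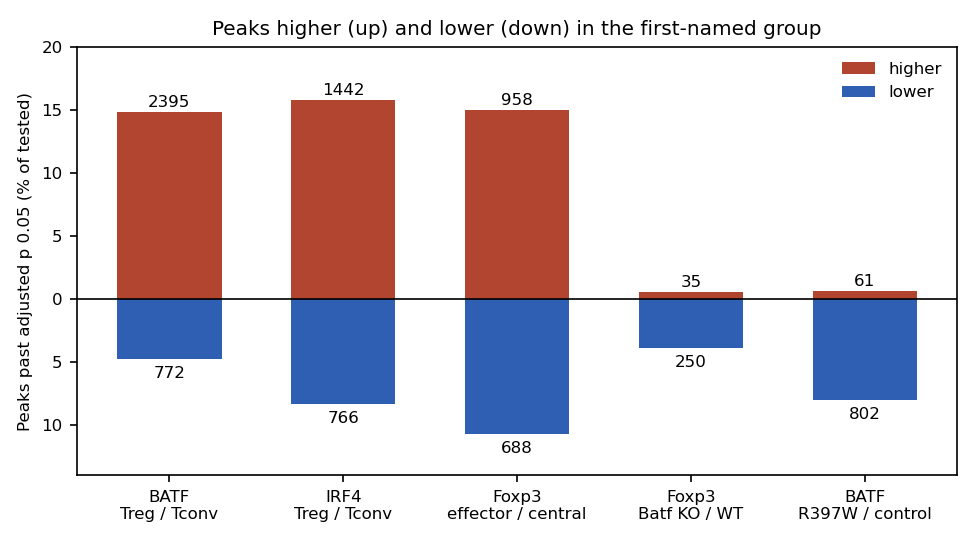
Bars show the share of tested peaks (y axis, percent) that were higher (red, upward) or lower (blue, downward) in the first-named group of each comparison (x axis) at an adjusted p under 0.05, with the number of peaks on each bar. Higher peaks were the more numerous in the Treg against Tconv comparisons (2395 and 1442 higher), and lower peaks were the more numerous in Batf knockout and R397W Treg cells (250 and 802 lower).

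BATF binding in Treg and Tconv cells was compared first. BATF was far higher in Treg cells at some peaks of genes that mark these cells. A peak within Ikzf2, which encodes the Treg factor Helios (chromosome 1, 69544194 to 69544594), reached 523 ± 107 in Treg and 44.7 ± 2.43 in Tconv cells (SD, n = 2 each). This was an 11.4-fold difference on the scale of value plus 1 (log2 fold change 3.51, SE 0.21, adjusted p = 4.48e-08). A peak within Ctla4, an inhibitory receptor (chromosome 1, 60913314 to 60913714), stood at 583 ± 154 against 106 ± 8.97, or 5.36-fold. A peak 44460 bp from Nrp1, a surface receptor of Treg cells, stood at 418 ± 113 against 64.7 ± 0.547, or 6.26-fold. Within Foxp3 itself (chromosome X, 7583901 to 7584301) BATF was at 112 ± 4.7 in Treg cells and at 1.74 ± 2.46 in Tconv cells (adjusted p = 1.82e-05), where 3 reads make a value of 2.14 or 3.48.

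Of 16109 BATF peaks, 2395 were higher and 772 lower in Treg cells, with median log2 fold changes of 1.83 and -1.36, near 1397 and 626 genes. Under quantile normalisation, which took the median log2 fold change of all peaks from -0.0267 to -0.131, the split was 2086 higher and 1291 lower. Among peaks above the 25th percentile of mean value the counts were 1443 and 328. Among strong peaks, large rises were within Jak2, a cytokine receptor kinase (329 ± 9.1 against 25.3 ± 17.7), and near the chemokine receptor gene Ccr1 (494 ± 147 against 39.5 ± 24.6). The largest fall among them was within Gramd3, at 40.9 ± 6.7 in Treg and 182 ± 45 in Tconv cells (log2 fold change -2.11, SE 0.26, adjusted p = 2.18e-05). Peaks within Atp9b and near Abhd2 fell by 1.65 and 1.47 on the log2 scale. The strongest peaks of several genes of naive or resting T cells did not pass the test. Lef1 stood at 216 ± 42.9 against 174 ± 0.996 (adjusted p = 0.338) and the peak near Tcf7 at 314 ± 83.2 against 261 ± 28.1 (adjusted p = 0.465). Of all 20 peaks of Lef1, however, 8 were lower in Treg cells and 1 was higher. The peak near Ccr7 stood at 178 ± 68.9 against 175 ± 40.9 (adjusted p = 0.985).

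Among the Treg core genes, 41 of 56 BATF peaks rose and 1 fell (47 and 3 adjusted over the list alone). As a list they stood above other peaks (camera, adjusted p = 5.87e-21; adjusted p = 0.0701 with an estimated correlation). Among effector Treg genes, 75 of 109 peaks rose and 3 fell (77 and 4 adjusted over the list alone). Their camera adjusted p was 2e-20, and adjusted p = 0.0701 with an estimated correlation. Examples are a peak 25928 bp from the cytokine gene Il10 (372 ± 76.1 against 65.3 ± 16.8, 5.66-fold) and a peak 868 bp from the chemokine receptor gene Ccr8 (142 ± 13.6 against 16.2 ± 1.72, 8.3-fold). Others lay near Bhlhe40, a helix-loop-helix factor (204 ± 53.4 against 7.1 ± 5.11), and near Tnfrsf9, the costimulatory receptor 4-1BB (286 ± 32.4 against 22.6 ± 10.7). Of the peaks of AP-1, BATF and IRF factor genes, 21 of 78 rose and 2 fell (24 and 3 adjusted over the list alone), among them peaks near Fosb and Atf3. Their camera adjusted p was 0.00188, and adjusted p = 0.126 with an estimated correlation. Of T helper lineage genes, 15 of 40 peaks rose and 2 fell (16 and 3 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.132 with an estimated correlation). Of T cell receptor signalling genes 36 of 131 peaks rose and 4 fell (41 and 4 adjusted over the list alone; adjusted p = 5.18e-05, and adjusted p = 0.0821 with an estimated correlation). A peak near Dusp4, a phosphatase of MAP kinases, was among them (165 ± 5.28 against 6.61 ± 2.77). Central or naive T cell genes (40 of 184 peaks higher and 17 lower, 44 and 21 adjusted over the list alone) did not stand apart from other peaks (camera adjusted p = 0.217). Neither did Foxp3 partner factors (28 of 131 higher and 14 lower, 29 and 15 adjusted over the list alone; adjusted p = 0.337).

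Markers of other cell types had few BATF peaks. A peak within the B cell factor gene Pax5 was higher in Treg cells (66.6 ± 12.8 against 10.1 ± 2.15). So were peaks near the myeloid factor genes Cebpa (43.2 ± 0.44 against 3.3 ± 1.39) and Cebpb (287 ± 22 against 164 ± 29.3), the latter call being lost without a trend of the spread on the mean (adjusted p from 6.75e-05 to 0.068 over the alternatives). A peak near Prf1, the perforin gene of CD8 and NK cells, was lower (7.2 ± 5.79 against 55.8 ± 18.1). In all, 1 of 3 B cell marker peaks and 2 of 5 myeloid marker peaks were higher (1 and 3 adjusted over the list alone). Of 9 CD8 and NK marker peaks, 1 was higher and 2 were lower (1 and 3 adjusted over the list alone). Of 23 peaks of housekeeping genes limma and edgeR called 0, with 3 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.967, downward, against a median log2 fold change of 0.10 and a mean of 0.06).

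IRF4 binding in the same pair of cell types was compared next. IRF4 was also higher in Treg cells at some peaks of Treg genes. The peak within Ikzf2 stood at 285 ± 18.9 in Treg and 84.9 ± 9.2 in Tconv cells (SD, n = 4 each; log2 fold change 1.74, SE 0.19, adjusted p = 1.09e-06). A peak 20642 bp from Nrp1 stood at 41.3 ± 10.9 against 5.82 ± 2.31, or 6.27-fold. A peak 51225 bp from Dusp4 stood at 145 ± 35.8 against 19.6 ± 7.88, or 7.3-fold, and a peak within Nfil3, a leucine zipper factor, at 122 ± 15.5 against 21.8 ± 10.1, or 5.8-fold. IRF4 fell by 2.04 on the log2 scale near the cytokine gene Il21 (6.96 ± 2.24 against 32 ± 10.1). It fell by 2.30 within Il12rb2, an interleukin-12 receptor subunit (6.87 ± 4.61 against 34.4 ± 12.3).

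Of 9134 IRF4 peaks, 1442 were higher and 766 lower in Treg cells, with median log2 fold changes of 1.64 and -1.23. The largest rise among strong peaks was within Fam185a (94.6 ± 19.8 against 5.3 ± 2.88, log2 fold change 4.08, SE 0.38). The largest fall was within Tnks (6.07 ± 1.9 against 73.9 ± 10.8, log2 fold change -3.44, SE 0.32). Treg core genes had 18 of 33 peaks higher (18 adjusted over the list alone; camera adjusted p = 1.55e-06, and adjusted p = 0.0743 with an estimated correlation). Effector Treg genes had 33 of 89 higher and 2 lower (41 and 5 adjusted over the list alone; adjusted p = 4.69e-06, and adjusted p = 0.0573 with an estimated correlation). Among them were peaks near Bhlhe40 (56.4 ± 6.53 against 12.5 ± 5.06) and Tnfrsf9 (64.7 ± 11.4 against 17.9 ± 5.06). The other lists had camera adjusted p of 0.608 or more. T helper genes had 10 of 38 peaks higher and 6 lower (12 and 6 adjusted over the list alone). Foxp3 partner factors had 8 of 66 higher and 11 lower (8 and 11 adjusted over the list alone), with a fall within Runx1, a runt-domain factor (24.7 ± 6.05 against 58.1 ± 13.1). Central or naive T cell genes had 20 of 114 higher and 14 lower (22 and 19 adjusted over the list alone). AP-1, BATF and IRF factor genes had 8 of 54 higher and 2 lower (8 and 2 adjusted over the list alone), and T cell receptor signalling genes 13 of 85 higher and 3 lower (12 and 3 adjusted over the list alone). The peaks within Il2ra (48.5 ± 15.3 against 45.5 ± 15.3, adjusted p = 0.844) and near Tnfrsf18 (57.9 ± 14.3 against 39.4 ± 5.61, adjusted p = 0.132) did not pass the test. Without Treg library 1 the Tnfrsf18 peak was higher past the threshold (adjusted p = 0.0416, the others up to 0.322). Of the markers of other cells, the Pax5 peak was higher for IRF4 as well (33 ± 11.3 against 15 ± 10.3). That call was lost without Treg library 1 or 3 or Tconv library 2 or 3 and without a trend of the spread, with adjusted p from 0.00643 to 0.0978 over the alternatives. Of the 10 housekeeping peaks that near Rpl13a, a ribosomal protein gene, was lower (16.2 ± 2.95 against 30.8 ± 8.94). It was lost without Treg library 1, 3 or 4, without Tconv library 2, 3 or 4 and without a trend of the spread (adjusted p from 0.029 to 0.18).

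**Figure D2:**
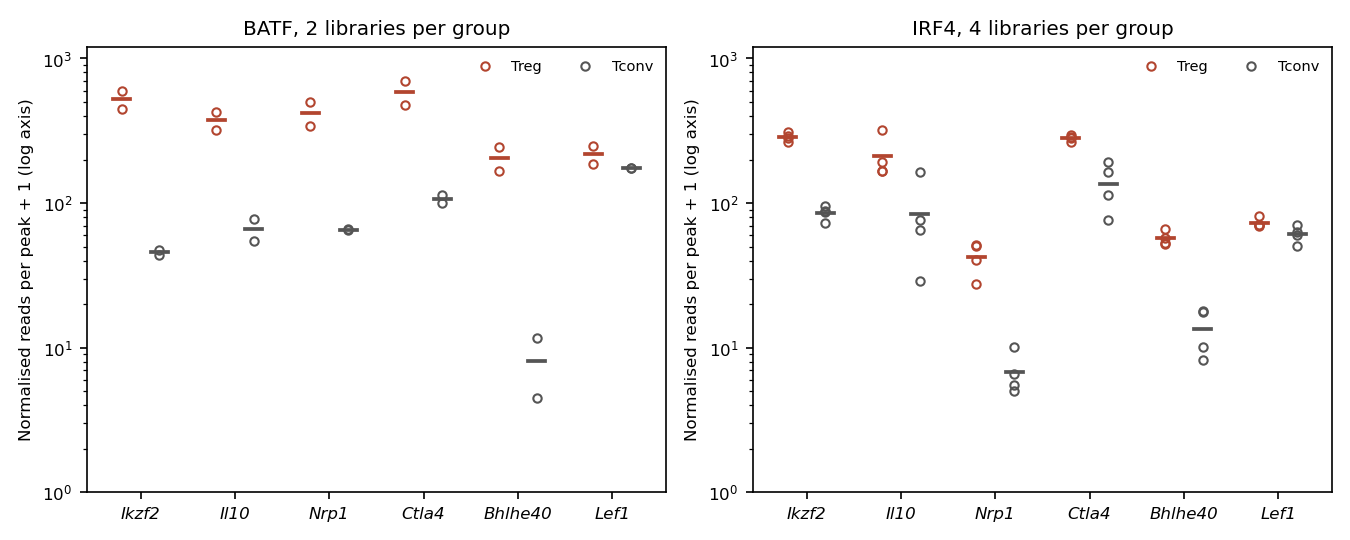
Circles are single libraries and bars are group means of normalised reads per peak plus 1 (y axis, log scale) for BATF (left, 2 libraries per group) and IRF4 (right, 4 libraries per group) in Treg (red) and Tconv cells (grey), at 1 peak for each of 6 genes (x axis). Treg values lie above all Tconv values at Ikzf2, Nrp1, Ctla4 and Bhlhe40 in both panels. The Lef1 peaks shown did not pass the test (limma, adjusted p = 0.338 for BATF and 0.408 for IRF4). Of all 20 BATF peaks of Lef1, 8 were lower and 1 higher in Treg cells.

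BATF and IRF4 shared many of their sites and of their differences between these cells. Of the IRF4 peaks 76.0% overlapped a BATF peak, and of the BATF peaks 43.0% overlapped an IRF4 peak. Over 6922 matched peaks, 903 of the 944 with higher IRF4 in Treg cells also had higher BATF, where 233 would be shared by independent lists. Of the 597 matched peaks with lower IRF4, 157 had lower BATF, against 24.2 for independent lists (Fisher's exact test, two-sided, adjusted p = 2.35e-97, peaks taken as independent). The log2 fold changes correlated across peaks with Pearson r = 0.83 and Spearman rho = 0.70. Peaks are not independent replicates, and 10 pairs of comparisons were computed in this way. IRF4 peaks without a BATF peak were higher in Treg cells at 497 of 2189 sites, or 22.7%, and those on a BATF peak at 945 of 6945, or 13.6%. The class difference was past the threshold (camera p = 0.0203, and p = 0.000147 with an estimated correlation). It was lost among the IRF4 peaks above the median value (p = 0.889) and with a reciprocal overlap of 50% (p = 0.0592), both with the preset correlation.

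The Foxp3 experiments asked how Foxp3 binding differs between effector and central Treg cells and how it depends on BATF. In effector Treg cells, Foxp3 was higher at many peaks near genes of effector Treg cells and lower at many near genes of naive and central T cells, though neither list passed with an estimated correlation (camera adjusted p = 0.112 for both). A peak 20094 bp from Maf, a leucine zipper factor, stood at 50.1 ± 0.946 in effector and 2.44 ± 0.311 in central Treg cells (SD, n = 2 each; adjusted p = 5.44e-07), the latter from 2 and 3 reads. A peak within Nfil3 stood at 41.4 ± 8.35 against 3.48 ± 0.728. A peak within Satb1, a chromatin organiser (chromosome 17, 51800210 to 51800610), stood at 3.98 ± 1.54 against 68.1 ± 19.1 (log2 fold change -3.80, SE 0.33, adjusted p = 2.79e-08). A peak 12258 bp from Tgfbr2, a TGF-beta receptor subunit, stood at 10.5 ± 2.29 against 90.1 ± 35.1 (-2.95). The peaks within Foxp3 (68.2 ± 28.4 against 72 ± 11.4, adjusted p = 0.788) and Il2ra, the interleukin-2 receptor alpha chain (81.2 ± 1.87 against 93.8 ± 2.64, adjusted p = 0.598), did not pass the test.

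Of 6396 Foxp3 peaks, 958 were higher and 688 lower in effector than in central Treg cells, with median log2 fold changes of 1.61 and -1.29. The counts were 652 and 429 without effector library 1, 577 and 453 without effector library 2, 684 and 443 without central library 1, and 756 and 418 without central library 2. Under quantile normalisation they were 1075 and 1062. Of the effector Treg genes, 35 of 70 peaks rose and 3 fell (36 and 3 adjusted over the list alone; camera adjusted p = 5.85e-08, and adjusted p = 0.112 with an estimated correlation). These included peaks 14000 bp from Il10 (31.7 ± 9 against 3.19 ± 0.738) and within Tigit, an inhibitory receptor (229 ± 28.8 against 68.5 ± 12.1). Others lay within Il1rl1, the receptor of interleukin 33 (32.6 ± 1.25 against 5.26 ± 0.0975), and near Klrg1 (39.4 ± 5.18 against 9.84 ± 8.68). Of the central or naive T cell genes, 48 of 108 peaks fell and 8 rose (52 and 11 adjusted over the list alone; adjusted p = 2.66e-11, and adjusted p = 0.112 with an estimated correlation). Besides Satb1 and Tgfbr2 they included a peak within Foxp1, a forkhead factor (29.8 ± 11.7 against 190 ± 27.3), and within Lef1, a factor of naive T cells (20.5 ± 2.06 against 73.6 ± 8.06). The Foxp3 partner factors share Satb1, Lef1, Tcf7, Ets1 and Foxo1 with that list. Of their peaks, 24 of 65 fell and 5 rose (26 and 5 adjusted over the list alone; adjusted p = 1.73e-05, and adjusted p = 0.112 with an estimated correlation).

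Of the T helper genes 12 of 31 Foxp3 peaks rose and 2 fell in effector Treg cells (12 and 2 adjusted over the list alone; camera adjusted p = 0.0411, and adjusted p = 0.414 with an estimated correlation). Examples lay near the interleukin-2 gene Il2 (46.5 ± 8.44 against 7.04 ± 0.533) and within Stat4, a signal transducer (34.2 ± 7.12 against 6.81 ± 5.44). Treg core genes went both ways, with 11 of 51 peaks higher and 3 lower (11 and 3 adjusted over the list alone; adjusted p = 0.227). The higher ones included peaks near Nrp1 (168 ± 11.5 against 20.6 ± 2.9) and near Nt5e, the ectonucleotidase CD73 (31.4 ± 0.377 against 2.74 ± 1.78). T cell receptor signalling genes had 13 of 66 higher and 7 lower (13 and 8 adjusted over the list alone; adjusted p = 0.36), and AP-1, BATF and IRF factor genes 4 of 22 higher and 3 lower (4 and 4 adjusted over the list alone; adjusted p = 0.764). A peak near Klrb1c, an NK cell receptor gene, was also higher (62.5 ± 7.8 against 23.7 ± 4.16).

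In Treg cells without BATF, Foxp3 was lower at a limited set of sites. No Foxp3 peak was assigned to Batf, so these values do not check the knockout itself. The peak 44450 bp from Nrp1 (chromosome 8, 128549726 to 128550126) fell from 118 ± 21.6 in wild-type to 7.55 ± 2.06 in knockout Treg cells (SD, n = 2 each). This was a 14.1-fold difference (log2 fold change -3.81, SE 0.28, adjusted p = 3.61e-09). A peak 61980 bp from Ankrd46 fell from 156 ± 1.55 to 8.94 ± 1.73, and a peak 2341 bp from Bach2, a transcriptional repressor, from 80.4 ± 12.1 to 12 ± 1.19. Peaks within Ets1, a T cell factor, and Ikzf2 fell from 56.3 ± 14.7 to 6.67 ± 5.12 and from 91.9 ± 5.9 to 19 ± 10.5. These 5 calls were kept under every alternative run. The strongest Foxp3 peaks of 21 of the 22 focus genes that had one did not pass the test. Among them were those within Il2ra (149 ± 36.3 in knockout against 160 ± 11.8, adjusted p = 0.866), Foxp3 (99.7 ± 24.6 against 143 ± 1.5, adjusted p = 0.331) and Tigit (227 ± 84.4 against 402 ± 17.9, adjusted p = 0.0515). The Tigit peak was lower past the threshold under 6 of 14 alternatives, among them edgeR (adjusted p = 0.0283) and the fit without knockout library 1 (adjusted p = 0.00313). Over all of them its adjusted p ran from 0.00313 to 0.445.

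Of 6396 Foxp3 peaks, 250 were lower and 35 higher in knockout Treg cells, with median log2 fold changes of -1.89 and 1.35. The counts moved with single libraries, to 108 lower and 27 higher without wild-type library 1, 89 and 19 without wild-type library 2, and 462 and 109 without knockout library 1. Quantile normalisation gave 165 lower and 9 higher, and a fit of only these 4 libraries 208 and 12. Effector Treg genes had 10 of 70 peaks lower and 1 higher (15 and 2 adjusted over the list alone; camera adjusted p = 0.00161, and adjusted p = 0.765 with an estimated correlation). The peaks near Maf (7.55 ± 2.06 against 33 ± 6.56) and within Nfil3 (40.7 ± 15.7 against 125 ± 8.48) were among the lower ones. The call at Maf was lost without wild-type library 2 (adjusted p = 0.126, the others down to 0.000331). That at Nfil3 was lost without wild-type library 1 (adjusted p = 0.0691, the others down to 3.33e-05). The higher peak was near Ccr2, a chemokine receptor gene (208 ± 81.8 against 82.2 ± 11.1). It was lost without wild-type library 1 or 2, without knockout library 1, without a trend of the spread and under quantile normalisation, with adjusted p from 0.000628 to 0.186 over the alternatives.

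Central or naive T cell genes stood above other Foxp3 peaks in the knockout as a list (median log2 fold change 0.25; camera adjusted p = 0.0143, and adjusted p = 0.765 with an estimated correlation). The peaks that passed the test alone, 3 of 108 (3 adjusted over the list alone), were lower, namely those near Bach2, within Ets1 and within Foxp1. The call at Foxp1 was lost without a trend of the spread, without either wild-type library or without knockout library 2 (adjusted p from 3.81e-06 to 0.235). Treg core genes had 3 of 51 peaks lower (3 adjusted over the list alone; adjusted p = 0.791), with a median of 0.06 and a mean of -0.14. T helper genes had 1 of 31 lower (4 adjusted over the list alone) and Foxp3 partner factors 2 of 65 (2 adjusted over the list alone), both with a camera adjusted p of 0.314. AP-1, BATF and IRF factor genes had 1 of 22 lower (1 adjusted over the list alone; adjusted p = 0.866, median 0.11, mean -0.06). T cell receptor signalling genes had 2 of 66 lower (2 adjusted over the list alone; adjusted p = 0.791). The largest rise among strong peaks was within Cmss1, at 86.3 ± 19.9 against 27.5 ± 13.1 (log2 fold change 1.68, SE 0.34, adjusted p = 0.00325). Without wild-type library 1 its adjusted p was 0.107, the others down to 0.000212.

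**Figure D3:**
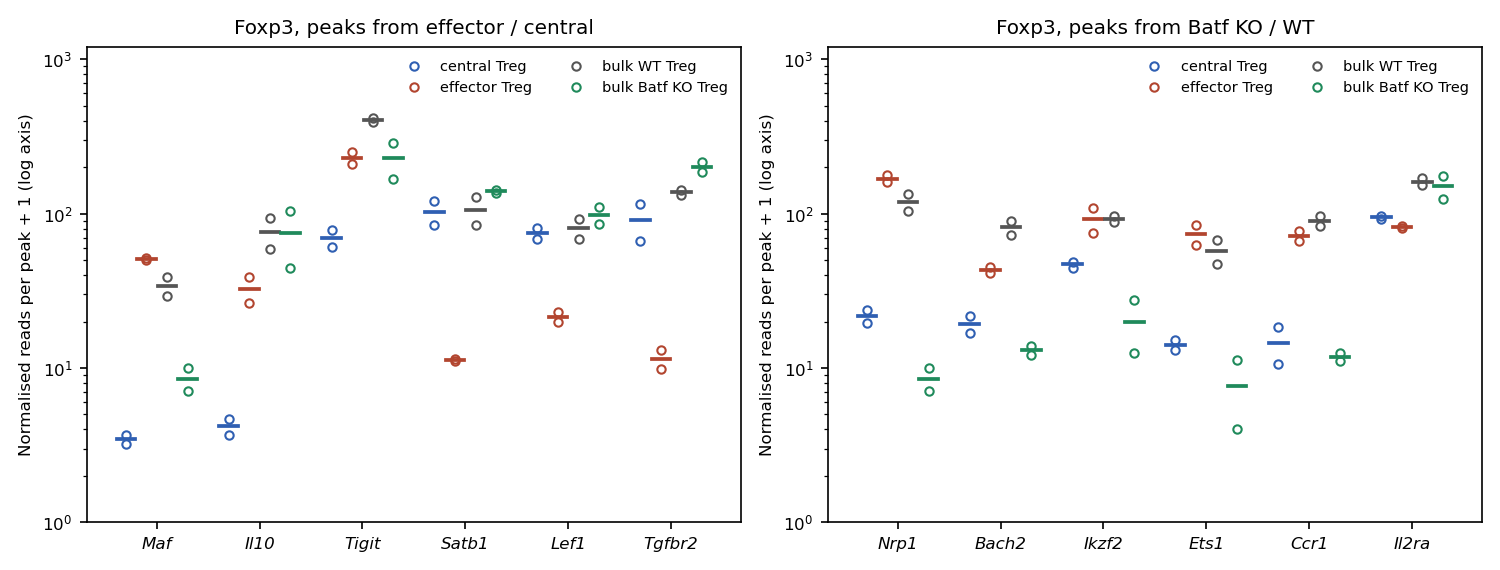
Circles are single libraries (2 per group) and bars are group means of normalised Foxp3 reads per peak plus 1 (y axis, log scale) in central (blue), effector (red), bulk wild-type (grey) and bulk Batf knockout Treg cells (green), at peaks taken from the effector against central comparison and from the knockout comparison (separate panels, genes on the x axis). At Nrp1 the knockout mean of 7.55 lies under the central Treg mean of 20.6, while the effector and wild-type means are 168 and 118.

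The sites that lost Foxp3 without BATF were largely those with more Foxp3 in effector Treg cells. Of the 250 lower peaks 206 were higher in effector than central Treg cells, against 37.4 for independent lists (Fisher's exact test, adjusted p = 8.75e-132). Across all Foxp3 peaks the log2 fold changes of these comparisons, which share no library, correlated with Pearson r = -0.55 and Spearman rho = -0.44. Of the Foxp3 peaks 48.2% overlapped a BATF peak and 39.7% an IRF4 peak. Foxp3 was lower in the knockout at 163 of 3081 peaks on a BATF peak (5.29%) and at 87 of 3315 others (2.62%). As classes the difference was small, with median log2 fold changes of 0.01 and 0.10 (camera p = 0.037, and p = 0.058 with an estimated correlation). It gave p = 0.193 against the BATF peaks above their median value and p = 0.212 among the Foxp3 peaks above theirs, with the preset correlation. With that correlation the call was also lost without wild-type library 2 (camera p = 0.419) or knockout library 1 (camera p = 0.0695). The mean effector against central difference was not set apart by BATF overlap (camera p = 0.61 with the preset correlation), where peaks went both ways. On BATF peaks 491 of 3081 (15.9%) were higher and 400 (13.0%) lower in effector Treg cells, and among the others 467 of 3315 (14.1%) and 288 (8.69%). The difference between these shares was not tested.

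The R397W experiment asked how BATF binding depends on Foxp3. BATF was lower in R397W Treg cells at some peaks of Treg and effector Treg genes. The peak 44469 bp from Nrp1 stood at 81 ± 18.5 in R397W and 317 ± 45.2 in control Treg cells (SD, n = 2 each), 3.91-fold lower (log2 fold change -1.97, SE 0.24, adjusted p = 0.000557). A peak within Rora, a nuclear receptor gene (chromosome 9, 69339820 to 69340220), stood at 3.28 ± 2.22 against 67.2 ± 7.73 (adjusted p = 0.00293). With 1 and 7 reads in the R397W libraries, the size of that fold is not given. Peaks within Gxylt2 (26.6 ± 8.27 against 172 ± 55.4) and near Snx13 (18.1 ± 8.69 against 134 ± 25.8) were lower too. The calls at Rora, Gxylt2 and Snx13 were kept under every alternative run, and that at Nrp1 was lost when the spread was not modelled as a function of the mean (adjusted p = 0.0563, the others down to 5.25e-06). BATF did not pass the test within Foxp3 (63.3 ± 29.1 against 101 ± 5.69, adjusted p = 0.177) or near Ctla4 (19.5 ± 0.911 against 41.4 ± 4.73, adjusted p = 0.177). Nor did the strongest peak near Il10 (220 ± 79 against 284 ± 0.158, adjusted p = 0.335) or the peak within Lef1 (123 ± 18.8 against 148 ± 30.4, adjusted p = 0.607). Of all 7 BATF peaks of Il10, however, 3 were lower with R397W and 0 higher.

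Of 9973 BATF peaks, 802 were lower and 61 higher in R397W Treg cells, with median log2 fold changes of -1.85 and 1.46. These counts depended on single libraries, being 459 and 1 without R397W library 1, 610 and 6 without R397W library 2, 468 and 182 without control library 1, and 124 and 17 without control library 2. The last is the shallowest of the table, with 144319 reads in peaks. With all 8 libraries of the table in the fit the counts were 795 and 219, under quantile normalisation (which took the median log2 fold change of all peaks from -0.0157 to 0.132) 482 and 58, without a trend of the spread 160 and 11, and with edgeR 836 and 131. Of the effector Treg genes 24 of 79 peaks were lower (33 adjusted over the list alone; camera adjusted p = 5.48e-10, and adjusted p = 0.241 with an estimated correlation). The peaks within Nfil3 (65.6 ± 13 against 180 ± 53.7) and near Bhlhe40 (49 ± 5.63 against 128 ± 10.3) were among them. Of the T helper genes 9 of 35 were lower (13 adjusted over the list alone; adjusted p = 0.00196, and adjusted p = 0.241 with an estimated correlation). They included a peak within Gata3, a zinc finger factor (23.4 ± 8.98 against 73.3 ± 0.998). The calls at Nfil3, Bhlhe40 and Gata3 were each lost without control library 2, without 1 of the R397W libraries and without a trend of the spread, and that at Gata3 also without control library 1. Over the alternatives their adjusted p ran from 0.00143 to 0.11, from 0.00262 to 0.0905 and from 0.00656 to 0.13.

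Of the Treg core genes 4 of 25 BATF peaks were lower with R397W (9 adjusted over the list alone; camera adjusted p = 0.00534, and adjusted p = 0.241 with an estimated correlation). With genes taken within 20000 bp the mean difference of this list from other peaks went from -0.46 to -0.04 and its call was lost (adjusted p = 0.641, the others from 0.00549 to 0.241). Central or naive T cell genes had 8 of 88 lower (8 adjusted over the list alone; adjusted p = 0.998). AP-1, BATF and IRF factor genes had 6 of 41 lower (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.176), and T cell receptor signalling genes 5 of 52 (5 adjusted over the list alone; adjusted p = 0.184). Foxp3 partner factors had 3 of 55 lower and 1 higher (3 and 1 adjusted over the list alone; camera adjusted p = 0.912, upward, against a median log2 fold change of -0.02). Of 10 peaks of housekeeping genes limma and edgeR called 0, with 2 higher and 0 lower at an unadjusted p under 0.05. The peak near the myeloid gene Cebpa was lower (5.5 ± 1.9 against 35 ± 0.631), a call lost without R397W library 2 or either control library (adjusted p from 0.00833 to 0.184). Among higher peaks, that within Gramd3 stood at 81.9 ± 14.8 against 29.4 ± 2.38 (log2 fold change 1.43, SE 0.34, adjusted p = 0.016). It was lost without R397W library 1 and without a trend of the spread, with adjusted p from 0.00642 to 0.146 over the alternatives. Pseudocounts of 0.1 and 10 gave 38 and 107 higher peaks in place of 61.

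**Figure D4:**
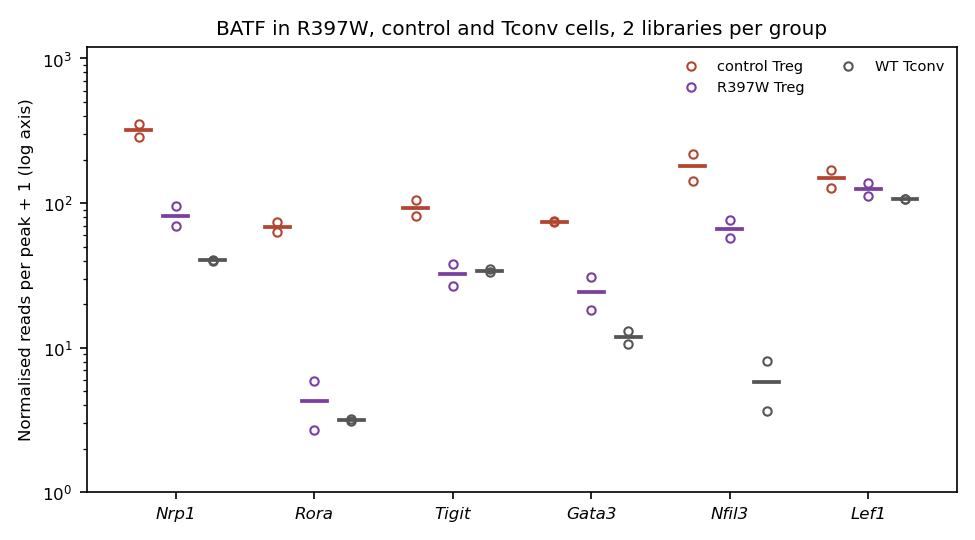
Circles are single libraries (2 per group) and bars are group means of normalised BATF reads per peak plus 1 (y axis, log scale) in control Treg (red), R397W Treg (purple) and wild-type Tconv cells (grey) of the same table, at 1 peak for each of 6 genes (x axis). R397W values lie between those of control Treg and Tconv cells at Nrp1, Gata3 and Nfil3, and the Lef1 peak did not pass the test (limma, adjusted p = 0.607).

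The sites that lost BATF with R397W were largely those with more BATF in Treg than Tconv cells. Of the 555 lower peaks that matched a peak of the Treg and Tconv experiment, 528 were higher in Treg cells, against 99.8 for independent lists. The log2 fold changes of these comparisons, which share no library, correlated across 8769 matched peaks with Pearson r = -0.69 and Spearman rho = -0.58. Of 56 matched peaks that were higher with R397W, 25 were lower in Treg than Tconv cells, against 3.99 for independent lists (Fisher's exact test, adjusted p = 1.64e-14). BATF peaks that overlapped a Foxp3 peak were lower with R397W at 324 of 2215 sites (14.6%) and others at 478 of 7758 (6.16%). This class difference was past the threshold (camera p = 0.000137, and p = 0.0259 with an estimated correlation). In Treg against Tconv cells, 970 of 3085 BATF peaks on a Foxp3 peak were higher (31.4%), against 1425 of 13024 others (10.9%; camera p = 1.78e-08, and p = 0.00144 with an estimated correlation). For IRF4 these shares were 556 of 2548 (21.8%) and 886 of 6586 (13.5%; camera p = 0.0148 with the preset correlation). This difference was lost with an estimated correlation (p = 0.0932) and against the Foxp3 peaks above their median value (p = 0.0926). All Foxp3 libraries came from Treg cells, while the BATF and IRF4 peak lists cover Treg and Tconv cells. Sites on a Foxp3 peak were thus picked as bound in Treg cells. An excess of peaks higher in Treg than Tconv cells could follow from that choice alone. Of the 555 matched peaks lower with R397W, 528 were higher in Treg cells. The larger share of peaks lower with R397W among those on a Foxp3 peak could thus follow from the same choice. Whether overlap with Foxp3 matters for the R397W losses beyond that was not tested.

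The losses with R397W and without BATF met at part of their sites. Of 324 BATF peaks that were lower with R397W and matched a Foxp3 peak, 112 had lower Foxp3 in Batf knockout Treg cells, against 25.1 for independent lists (Fisher's exact test, adjusted p = 5.89e-58). Of the same peaks 247 had higher Foxp3 in effector than central Treg cells, against 72.2. The peak near Nrp1 was lower both for BATF with R397W and for Foxp3 without BATF. Across 2211 matched peaks, the R397W log2 fold changes correlated with those of the knockout with Pearson r = 0.52 and Spearman rho = 0.49. They correlated with those of effector against central Treg cells with Pearson r = -0.69 and Spearman rho = -0.68. Of the 163 matched BATF sites with lower Foxp3 in the knockout, 155 had higher BATF in Treg than Tconv cells, against 51.2 for independent lists (adjusted p = 3.75e-70).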

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

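The background comparison of the mixture test, its checks at peaks higher in Tconv cells and in wild-type Treg libraries, the matching by peak strength, the values per library on and off BATF peaks, and for the third pattern the strength from both kinds of cells and the spread per library were tests chosen only after the result was seen.

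The first pattern is that BATF peaks lower in R397W Treg cells were mostly those higher in Treg than Tconv cells. Lower enrichment in the R397W libraries would lower peaks of like strength alike. The median log2 fold change was -1.85 at the lower peaks, which were picked for their fall. At 4174 peaks of matched strength that did not differ between Treg and Tconv cells it was 0.16 (95% bootstrap interval 0.14 to 0.18). The scaling holds the median of most peaks close to no change, so a fall common to all peaks would not show. The gap between these sets follows largely from how the lower peaks were picked, so it does not decide on lower enrichment. It shows only that peaks of like strength did not, as a set, fall with them. At the 1574 peaks higher in Treg cells, picked without the R397W libraries, the median was -0.94, but strength was not matched there. Tconv cells among the sorted R397W cells could also give the pattern, although the hCD2 gate would remove them. The best single share, 64.9%, left deviations of 1.89 times the error variance (1.75 to 2.03), past the bound of 1.5 set in advance. But 4176 peaks of matched strength that no mixture moves gave 1.73 (1.64 to 1.83), so that bound could not single out a mixture. The wild-type Treg libraries of the first experiment gave 0.87 about their median against the same controls, at the peaks higher in Treg cells. The R397W libraries thus varied more, also where no mixture acts, and the cause was not tested. The implied median share was 63.0% at peaks higher in Treg cells and 35.0% at the 624 peaks higher in Tconv cells (64.0% and 42.7%, and 64.3% and 46.7%, from sums over peaks chosen in 1 replicate, with Tconv values from the other), which goes against 1 common share, but the wild-type Treg libraries of the first experiment, set against the same controls in that way, gave 37.1% and 2.63%, and 23.0% and -4.80%. Between these wild-type libraries limma called 0 peaks higher and 1 lower in the controls (866 at an unadjusted p under 0.05). Only the gap between their shares was thus as wide as that with R397W. As that gap arises without R397W, these tests cannot tell apart Tconv cells and an effect of R397W on BATF binding. A smaller share of effector cells among the R397W Treg cells was not tested. Of 324 lower peaks that matched a Foxp3 peak, 247 had higher Foxp3 in effector than central cells, against 72.2 for independent lists. BATF was not measured in effector and central cells apart.

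The second pattern is that Foxp3 peaks lower in Batf knockout Treg cells were mostly those higher in effector than central Treg cells. Lower enrichment in the knockout libraries would lower peaks of like strength alike. The median log2 fold change was -1.89 at the lower peaks, which were picked for their fall. It was 0.10 (0.07 to 0.12) at 2949 peaks of matched strength that did not differ between effector and central cells. Here too the scaling fixes the level and the gap follows largely from how the lower peaks were picked, so it does not decide on lower enrichment. At all peaks higher in effector cells, picked by the effector against central comparison, the median was -0.58, but strength was not matched there. A smaller share of effector cells would lower effector-higher peaks alike on and off BATF peaks, but at matched fold change those on BATF peaks were lower by a difference of -0.40 (-0.49 to -0.30; camera p = 0.000355, and p = 0.262 with an estimated correlation), and -0.53 (-0.62 to -0.43) when matched for strength too. Bulk wild-type libraries stood higher on than off BATF peaks by 0.45 and 0.50, the knockout libraries by -0.03 and -0.07, and effector and central libraries by -0.07 to 0.04. As no mixture of effector and central profiles gives the bulk wild-type values, the bound of 0.2 set in advance for that difference was wrong, and a smaller effector share (with which goes that the 688 peaks higher in central cells rose by a median of 0.30, 0.27 to 0.33) and a direct need of Foxp3 for BATF cannot be told apart.

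The third pattern is that Foxp3 in bulk wild-type Treg cells lay above both effector and central values at 844 peaks (13.2%) and below both at 514 (8.04%). Knockout bulk cells lay above both at 824 and below both at 395, of which 630 and 178 were shared, although both kinds of bulk cells were set against the same effector and central libraries. A difference in enrichment would grow with peak strength, and the Spearman correlation across peaks of strength and difference was -0.12 (-0.15 to -0.10), or 0.04 with the libraries exchanged. That strength came from effector and central cells alone, which pulls the correlation down, so the bound of 0.1 set in advance could not decide. With strength from bulk cells too, and the difference from the other libraries, the correlation was 0.44 and 0.46. But effector and central values were averaged (Pearson r 0.34 to 0.37 between them), which narrows their spread and pulls this correlation up. Neither correlation thus decides on enrichment. Log2 values had SDs of 1.15 to 1.22 in bulk and 0.79 to 0.99 in effector and central libraries. A difference in enrichment, cells outside the gates and a difference in preparation cannot be told apart, the last 2 not having been tested, and no biological explanation was tested.

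For IRF4 between Treg and Tconv cells, only 1 of 35 splits of the 8 libraries, the real one, reached the 2208 called peaks with limma. The highest count of the other splits was 0. Each of those mixes Treg and Tconv libraries, which widens the spread within its groups and keeps its count low. Chance is thus unlikely for the calls as a whole, but 35 splits cannot exclude it. Single IRF4 libraries stood apart from the other 3 of their group at 4 peaks of 130 groups of values, where about 6.5 would by chance. Treg library 2 stood at 96.8 at the Bcl2 peak (others 43.8 to 51.1) and at 20.6 near Rpl13a (others 14.5 to 14.96). Treg library 3 stood at 80.1 at the Lef1 peak (others 68.2 to 70.1), and Tconv library 3 at 163 at the Bach2 peak (others 325 to 340). The second BATF table also holds the Treg and Tconv libraries of the first, outside the R397W comparison, and there 1977 peaks were higher and 482 lower in Treg cells.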

How the results depend on the processing

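Tests by edgeR, the fit of all 8 libraries of the second BATF table and the class tests within the stronger Foxp3 or IRF4 peaks were chosen only after the result was seen. No result changed direction past its threshold under any alternative run. Of 286 named peaks 175 were called, 119 of them under every alternative run and 129 when left-out libraries are set aside. The cause of the changes below was not tested, unless fewer peaks or libraries make it plain. The classes by motif and the nearest transcription start site were not run. Recovery on simulated data was lowest for R397W, at 14% of 2-fold changes, and the shallowest library, with 144319 reads in peaks, is in that comparison. Whether its depth is the cause was not tested. A library alone in its group was assumed to vary like the others.

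The filter at the 25th percentile, which tests fewer peaks, left 1443 higher and 328 lower BATF peaks in Treg against Tconv cells and 17 higher Foxp3 peaks in the Batf knockout. Quantile normalisation gave 1291 lower BATF peaks, 9 higher and 165 lower Foxp3 peaks in the knockout, 1062 lower Foxp3 peaks in effector Treg cells and 482 lower BATF peaks with R397W. Only the 4 libraries of the knockout comparison gave 12 higher. For R397W, pseudocounts of 0.1 and 10 gave 38 and 107 higher, no trend of the spread 11 higher and 160 lower, edgeR 131 higher and all 8 libraries 219 higher.

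Leaving out 1 library gave 19 (without wild-type 2) to 109 (without knockout 1) higher and 89 (without wild-type 2) to 462 (without knockout 1) lower Foxp3 peaks in the knockout. It gave 577 (without effector 2) to 756 (without central 2) higher and 418 (without central 2) to 453 (without effector 2) lower in effector Treg cells. For R397W it gave 1 (without R397W 1) to 182 (without control 1) higher and 124 (without control 2) to 610 (without R397W 2) lower.

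The mean difference of Foxp3 log2 fold changes in the knockout, on minus off BATF peaks, was -0.0899 against the stronger BATF peaks (p = 0.193), -0.15 with an estimated correlation (p = 0.058) and -0.0828 among the stronger Foxp3 peaks (p = 0.212). Without 1 library it ran from -0.22 without wild-type 1 to -0.0749 without wild-type 2 (camera with a preset correlation, p = 0.419), and the call was also lost without knockout 1 (p = 0.0695). For IRF4 on Foxp3 peaks it was 0.12 against the stronger Foxp3 peaks (p = 0.0926) and 0.20 with an estimated correlation (p = 0.0932). For IRF4 on BATF peaks it was -0.249 with a reciprocal overlap of 50% (p = 0.0592) and -0.0242 among the stronger IRF4 peaks (p = 0.889), both by camera with a preset correlation. That overlap rule put 41.5% of BATF peaks on IRF4 peaks, 46.9% of Foxp3 peaks on BATF peaks and 73.2% of IRF4 peaks on BATF peaks. Peaks higher in both the knockout and R397W were 14.4 times those of independent lists under median-of-ratios scaling (Fisher's exact test, p = 0.00793), and 8.38 times as deposited (p = 0.113). As deposited this was 1 shared peak, against 0.119 for independent lists, among 11 and 24 matched higher peaks. With an estimated correlation 0 lists passed the threshold of camera in each of the 5 comparisons, where 5, 2, 2, 4 and 3 had passed. This loss need not come from peaks that vary together. For BATF at Treg core peaks the estimate was -0.0124, under the preset 0.01, yet the unadjusted camera p went from 5.34e-22 to 0.00686.

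The replicate number as a block gave 2655 higher and 1149 lower BATF peaks and 1569 and 856 IRF4 peaks in Treg against Tconv cells, 33 and 254 Foxp3 peaks in the knockout and 957 and 705 in effector Treg cells. Same-numbered libraries deviated together with r = 0.0882 for BATF, 0.0761 for the knockout and 0.139 for effector and central cells. For IRF4 r was 0.132, 0.0346, 0.0556 and 0.052, and Treg library 3 correlated best with Tconv library 4 (0.0576). IRF4 libraries of different numbers ran from -0.102 to 0.0576. All values of same-numbered libraries were positive but small, so a common preparation by number is neither shown nor excluded. No paired analysis was possible for R397W because it and its control share no replicate numbers in the labels.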

Other observations

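Which partner a Foxp3 site had, and the loci with several changed peaks below, were tests and choices made only after the result was seen. Foxp3 peaks that overlapped both a BATF and an IRF4 peak were lower in Batf knockout Treg cells at 154 of 2143 sites (7.19%). Those on an IRF4 peak alone were lower at 24 of 399 (6.02%), those on a BATF peak alone at 9 of 938 (0.959%) and those on neither at 63 of 2916 (2.16%). Among sites on a BATF peak, those with and without IRF4 differed (Fisher's exact test, two-sided, p = 1.38e-15, peaks taken as independent). Among the stronger Foxp3 peaks these were 76 of 1730 and 4 of 613 (Fisher's exact test, p = 9.01e-07). Sites on an IRF4 peak with and without BATF did not differ past the threshold (Fisher's exact test, p = 0.455). Sites on a BATF peak alone were lower less often than those on neither (Fisher's exact test, p = 0.0178), also among the stronger Foxp3 peaks (4 of 613 and 14 of 614, p = 0.0297). The classes also differed in the share of peaks higher in effector than central Treg cells. It was 18.9% on both, 25.1% on IRF4 alone, 9.17% on BATF alone and 12.6% on neither. Peaks lower in the knockout were largely effector-higher ones, and whether the partner matters beyond that was not tested.

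Several genes had many changed peaks. In effector against central Treg cells Foxp3 was lower at 10 of 10 peaks of Satb1 and at 12 of 21 of Foxp1, with 2 higher. It was higher at 7 of 8 peaks of Rora and 5 of 10 of Icos, a costimulatory receptor, and 3 of the 10 Icos peaks were lower in the Batf knockout. BATF was higher in Treg than Tconv cells at 10 of 10 peaks of Il10, 10 of 12 of Ctla4, 7 of 7 of Ikzf2, 7 of 7 of Bhlhe40 and 9 of 11 of Rora. It was lower at 8 of 20 peaks of Lef1, with 1 higher. With R397W, BATF was lower at 7 of 12 peaks of Rora, 3 of 6 of Icos and 3 of 7 of Il10.

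Other contrasts of the tables were not part of the comparisons above. R397W Treg cells had 1205 BATF peaks higher and 95 lower than Tconv cells. They had 40 higher and 170 lower than the Treg cells of the first BATF experiment. The R397W controls against those Treg cells had 0 higher and 1 lower with limma (866 at an unadjusted p under 0.05, edgeR not run). Bulk wild-type Treg cells had 1347 Foxp3 peaks higher and 919 lower than effector Treg cells, and 1624 and 1252 against central Treg cells. Batf knockout Treg cells had 1392 higher and 1086 lower than effector and 1385 and 846 against central Treg cells.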
